A study of Homo sapiens with 20 samples.

How the data were processed

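RNA sequencing was done on monocytes isolated from peripheral blood in sarcoidosis, an inflammatory disease that forms granulomas, small clusters of immune cells. Per the labels, isolated monocytes were cultured for 16 h at 37 °C with or without dexamethasone, a synthetic glucocorticoid, at 100 ng/mL. There were 10 libraries labelled untreated and 10 labelled dexamethasone. Messenger RNA was isolated on Dynabeads and libraries were made with a NEBNext directional kit, per the labels' protocols. The labels do not say whether the libraries of a group came from separate donors, so p-values measure the spread between these samples, part of which may be technical.

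The deposited table gave 1 value per gene and library. The submitters' processing notes name STAR, DESeq2 and the hg19 build, with no versions. The strand setting, annotation and counting tool were not given in the sources used here. The values deposited by the authors were CPM (reads of a gene scaled to the same total in each library): values were kept to 2 decimals, although the table's name speaks of counts. One of its 63678 rows held no values and was left out. The other 63677 rows carried 56636 gene names, and rows that shared a name were kept apart only where each had reads. Mitochondrial genes were listed at 0 in all 20 libraries. There were 24 names that were whole numbers, as a spreadsheet leaves when it turns a gene name into a date, and these were tested but not named.

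In every library the CPM values were whole multiples of the worth of 1 read, within a tolerance of 0.01 CPM for 100% of values. Reads were recovered from those steps, which gave 4888 to 39070879 reads per library. One read was worth 0.0256 CPM in the deepest library, 7.40 CPM in dexamethasone replicate 3 and 205 CPM in untreated replicate 8. The floor of 3 reads for a gene listed at 0 came to 22.2 CPM in dexamethasone replicate 3. Untreated replicate 8 held 4888 reads, of which 17 were of MALAT1, a nuclear RNA, and 0 were of B2M, where the other untreated libraries would give 31.5. No pair of libraries within a group held identical values, and the lowest chi-square per degree of freedom between libraries of a group was 6.96.

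Because the file held CPM, the test fixed for such values was used: limma 3.58.1 (limma-trend) on log2(CPM + 1) over all 20 libraries, for genes at 1 CPM or more in at least 10 libraries. Fold changes on that scale understate the change of low genes. A pair of fits was added after seeing the data. The first was edgeR 4.0.16 (quasi-likelihood test, TMM scaling, expression filter by group) on the recovered reads of 19 libraries, without untreated replicate 8, and is called the fit of reads. The second added a correction per library for the GC content and length of each gene (loess, span 0.3), and is called the corrected fit. GC content and length came from GENCODE 29 transcripts, matched by name, which belong to another build than hg19, so no coordinates are given. Of the genes called in the fit of reads, 92.2% had a GC value. The median log2 fold change of all genes was -0.02 in the fit of reads and 0.17 in the corrected fit. The corrected fit still tested each gene against no change, so that shift favored calls of higher genes over calls of lower ones. Higher calls made only after correction carry that limit, and so do lower calls lost after it. All adjusted p-values are Benjamini-Hochberg values, two-sided, with a threshold of 0.05. Means ± SD in CPM are over 9 untreated libraries, without replicate 8, and 10 dexamethasone libraries.

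The 37 gene lists, the test for CPM, a set of alternatives and the rule for named genes were set before the data were examined. Lists were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry, where at least 5 members were measured. For the edgeR fits, these tests used log2 CPM values with every library weighted alike, not the edgeR model. Their direction could therefore differ from the median fold change, as for platelet markers after correction (median 0.59, camera direction down, not called). The rule took NR3C1, FKBP5, TSC22D3, PER1 and ZBTB16 as checks of the treatment, the 12 highest and 12 lowest fold changes among called genes with a mean of at least 2 log2 CPM, the 4 smallest p-values in each direction, and up to 4 members with the smallest p from each list. Genes on the Y chromosome, XIST and entries without a symbol were left out. Applying the rule to the fit of reads as well was decided after seeing the data, and values are given for some of the 225 genes it took, picked after their values were seen. Metallothioneins, linker histones, granzymes, ribosomal proteins and HLA genes have near-identical relatives, and their values are uncertain because the counting may have split or dropped shared reads.

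The fits were tested on simulated reads with the real means, library sizes and dispersions and 200 changed genes. The 20-library fit called 2% of genes changed 2-fold and 26% of those changed 4-fold, over 12041 genes tested. The fit of reads called 45% and 87.6%, with 3.70% of its calls false, over 11826 genes. The corrected fit, on reads given the GC trends of the real libraries, called 42.4% and 81.4%, with 6.20% of calls false, over 10656 genes. On those GC-biased reads, the fit of reads without correction had 40.3% of its calls false. The trends put in were the ones the correction itself had fitted, so its gain over the fit of reads was built in. All of the trend was simulated as technical, so 40.3% is not an estimate for the real calls. Differences in library measures were compared with two-sided permutation tests of 100000 resamples. Alternatives covered DESeq2 1.42.0, voom, other scalings, filters, pseudocounts and thresholds, a block on the title number, reads thinned to equal depth, and leaving out each library. Calculations used R 4.3.3 and Python 3.11.15.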

Results

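The series measured gene expression in blood monocytes from sarcoidosis after 16 h of culture, in 10 libraries labelled untreated and 10 labelled dexamethasone. The question was which genes dexamethasone raised or lowered. Reads in genes ranged from 4888 to 39070879 in the untreated libraries and from 135108 to 3536896 in the dexamethasone libraries. Untreated replicate 8, with 4888 reads, held no usable profile. Over the other 19 libraries, log10 reads averaged 7.02 ± 0.45 (SD, n = 9) untreated and 6.03 ± 0.49 (SD, n = 10) with dexamethasone (permutation test, two-sided, p = 0.00019, adjusted p = 0.000633 over 10 library measures). Genes with at least 1 read averaged 26874 ± 4502 untreated and 16838 ± 4688 with dexamethasone (permutation p = 0.00014, adjusted p = 0.000633). Depth and treatment were therefore confounded, and genes at a few CPM were at or under the limit of detection in the shallow treated libraries. The share of reads from MALAT1 also differed, at 3.13 ± 0.46% untreated and 4.03 ± 0.81% with dexamethasone (permutation p = 0.005, adjusted p = 0.0125).

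**Figure D1:**
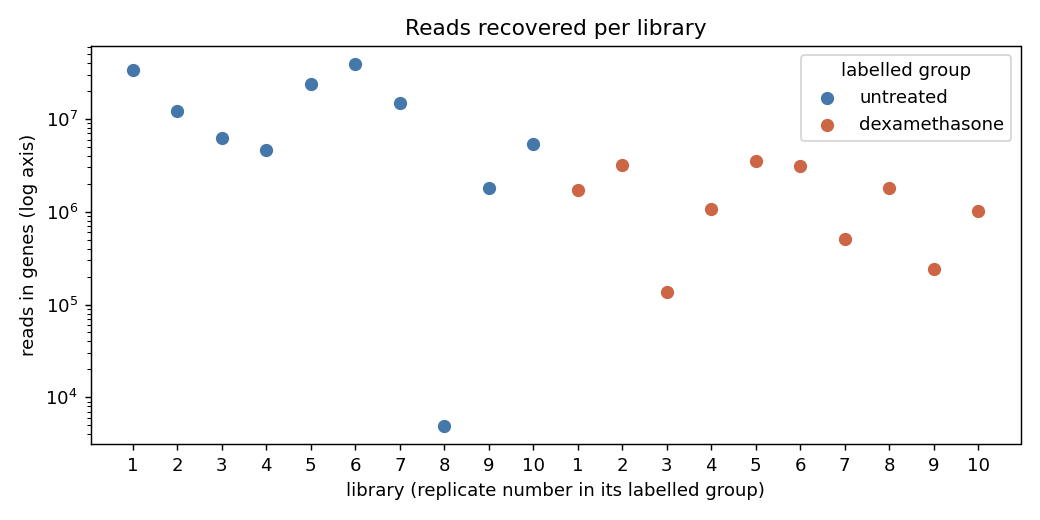
Reads in genes recovered for each library (log axis), with the replicate number on the horizontal axis and color for the labelled group. Untreated replicate 8 lies at 4888 reads, and the dexamethasone libraries span 135108 to 3536896.

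FKBP5, a chaperone gene switched on by the glucocorticoid receptor, checked the treatment labels. It averaged 270 ± 269 CPM (SD, n = 9) in untreated and 1333 ± 754 CPM (SD, n = 10) in dexamethasone libraries. In 2 libraries labelled dexamethasone FKBP5 was at 98.7 and 132 CPM, while the other 8 treated libraries held 751 to 2294. In 2 libraries labelled untreated it was at 683 and 792 CPM, and the other 7 untreated libraries with reads held 101 to 225. The values of these 4 libraries went against their labels, so groups below are named by label and every direction is that of the labels. NR3C1, the glucocorticoid receptor gene itself, stayed at 410 ± 91.7 and 407 ± 180 CPM (log2 fold change 0.03 ± 0.25 SE, adjusted p = 0.956 in the fit of reads).

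Across all 20 libraries, limma called 5 of 14817 genes, with 1146 at an unadjusted p under 0.05. ABLIM3, an actin-binding gene, was higher with dexamethasone, with a log2 fold change of 3.61 (adjusted p = 0.022). FCER2, the low-affinity IgE receptor CD23, was lower (-2.60), as were GZMM, a granzyme of cytotoxic lymphocytes (-2.83), HSD3B7, a bile acid synthesis enzyme (-2.40), and ST8SIA1, a ganglioside sialyltransferase (-2.37). ST8SIA1 averaged 8.53 CPM untreated and 0.262 CPM with dexamethasone, too low for the filter of the fit of reads. Without untreated replicate 8 the same test called 880 genes.

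The fit of reads over 19 libraries called 782 of 12049 genes, 336 higher and 446 lower with dexamethasone. The corrected fit called 180 of 10781 genes, 129 higher and 51 lower. Neither fit had a block on the title number, which changed the counts in each direction, as given with the processing alternatives. Both fits called 85 genes higher and 50 lower. The corrected fit alone called 44 higher and 1 lower, with the upward shift of its median gene given above. In the fit of reads, genes called higher had a median GC content of 40.2% and genes called lower 58.7%, against 47.6% for all genes. The log2 fold change correlated with GC content across genes (r = -0.44), where genes are not independent replicates. Within libraries, the correlation of expression deviation with GC averaged 0.237 ± 0.081 (SD, n = 9) untreated and -0.180 ± 0.132 (SD, n = 10) with dexamethasone (permutation p = 5e-05, adjusted p = 0.0005). Values below are from the fit of reads unless marked as corrected. Without the treated replicates 3 and 9, each under 300000 reads, the fit of reads called 2057 genes and the corrected fit 574. Without untreated 2 they called 438 and 23, and without untreated 6 they called 441 and 32. Without dexamethasone 3, 7, 9 or 10 the fit of reads called 1311, 1375, 1378 and 1108 genes, and the corrected fit 281, 435, 248 and 433. Of the genes named here, 16 kept their corrected call in 3 to 9 of the 19 corrected fits that left out a library: ACAP1, EGR2, FKBP5, FPR3, GZMA, HMGB3, IL32, LAG3, LAT, LCK, LTB, MT1X, MT2A, TIPARP, TNFAIP3 and ZBTB16.

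**Figure D2:**
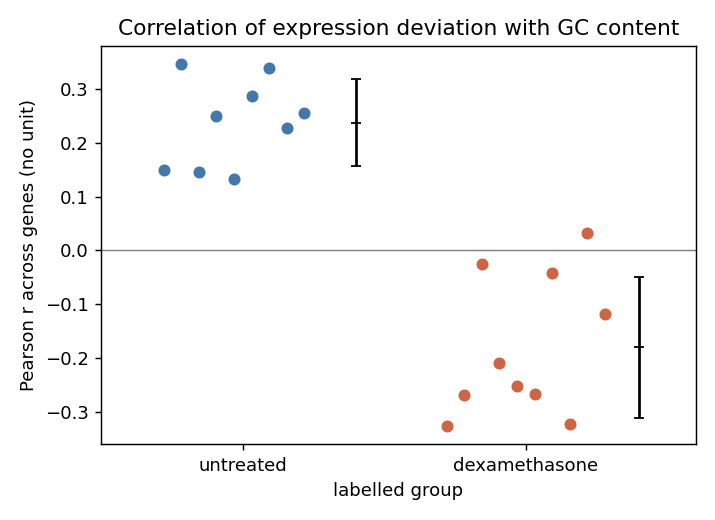
Pearson correlation across genes between the deviation of log2 expression from its mean over libraries and GC content, 1 point per library, with the mean and SD of each labelled group as bars. The 9 untreated libraries lie between 0.134 and 0.347, and the 10 dexamethasone libraries between -0.327 and 0.033.

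Of 22 measured known targets of the glucocorticoid receptor, 9 were called higher and 0 lower in the fit of reads (16 higher when adjusted over the list alone), and 11 were called higher in the corrected fit (17 adjusted over the list alone). FKBP5 rose by a log2 fold change of 2.31 ± 0.56 SE (adjusted p = 0.0202), and 2.45 ± 0.57 (adjusted p = 0.0353) after correction. ZFP36, which destabilises cytokine messages, rose from 234 ± 41.3 to 475 ± 234 CPM (1.01 ± 0.22, adjusted p = 0.012; corrected 1.73, adjusted p = 0.0123). TXNIP, an inhibitor of thioredoxin, rose from 574 ± 262 to 1702 ± 963 CPM (1.56, adjusted p = 0.0131; corrected 1.65, adjusted p = 0.0238). TIPARP, a mono-ADP-ribosyltransferase, rose by 0.87 (adjusted p = 0.0141; corrected 0.93, adjusted p = 0.0422). IRS2, an adaptor of insulin signalling, rose from 81.3 ± 51.1 to 192 ± 79.2 CPM (1.27, adjusted p = 0.0379; corrected 1.84, adjusted p = 0.0104), a call kept in 10 of 19 fits of reads without a library. The clock gene PER1 had values of 0.78 (adjusted p = 0.0874) and 1.45 (corrected, adjusted p = 0.0155), and the transcription factor ZBTB16 was called after correction alone (1.70, adjusted p = 0.0486; 0.0528 in the fit of reads). TSC22D3, which encodes the leucine zipper GILZ, was not called in either fit (1.68, adjusted p = 0.0717; corrected 2.22, adjusted p = 0.0643). The list test gave camera adjusted p = 3.09e-09 in the fit of reads, and adjusted p = 0.0816 with an estimated correlation. Fry gave adjusted p = 0.0308, and adjusted p = 0.00489 after correction. Fry results for the other lists are given with the processing alternatives. Leaving out single libraries ended the call of FKBP5 in 12 of 19 corrected fits, with adjusted p up to 0.0812, but in 0 of 19 fits of reads.

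**Figure D3:**
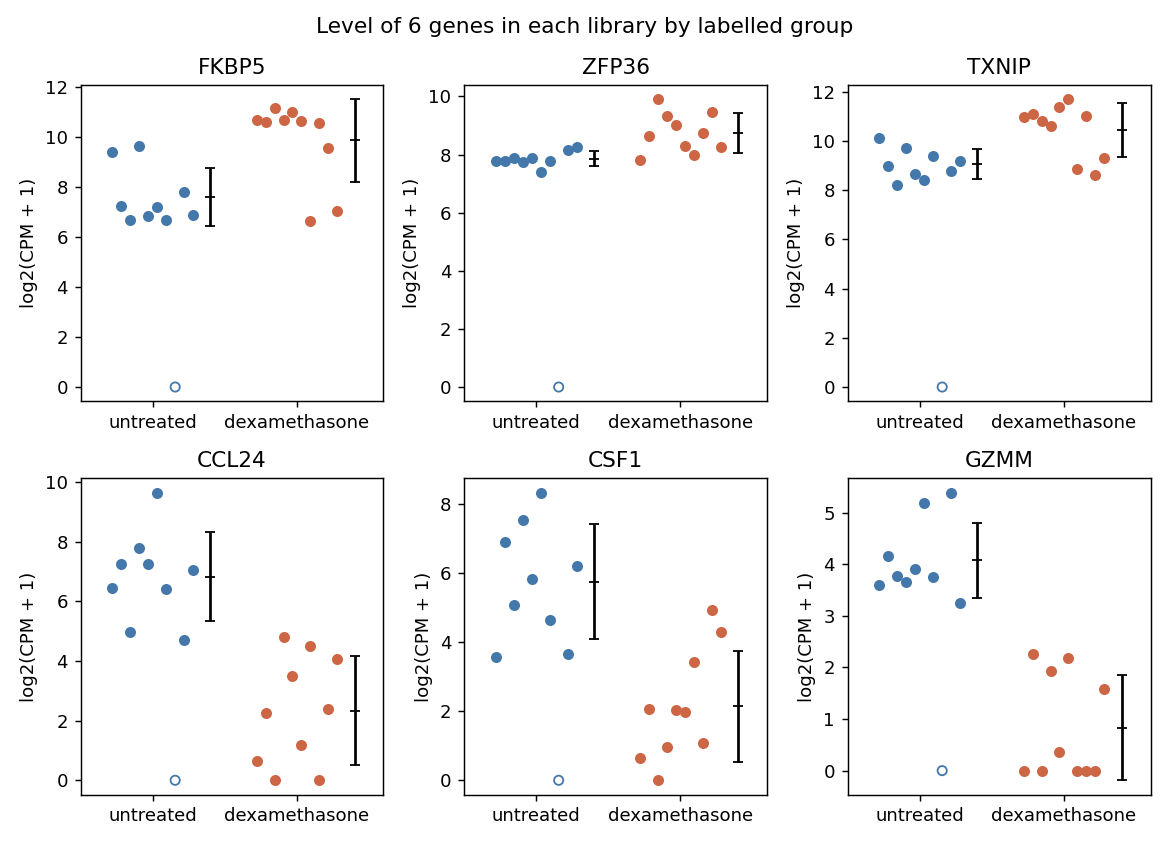
log2(CPM + 1) of 6 genes in each library by labelled group, with the mean and SD as bars. Open circles mark untreated replicate 8, which the bars leave out; FKBP5 lies at 98.7 and 132 CPM in 2 libraries labelled dexamethasone.

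Feedback regulators of inflammation included 2 genes called higher of 19 measured in the fit of reads and 3 after correction (4 and 7 adjusted over the list alone). DUSP1, a phosphatase that switches off MAP kinases, rose by 0.81 (adjusted p = 0.0487; corrected 1.37, adjusted p = 0.0219). That call held in 6 of 19 fits of reads that left out a library, and in 17 of 19 corrected fits. TNFAIP3, a ubiquitin-editing brake on NF-kB, was called only after correction (1.06, adjusted p = 0.0454). The list had camera adjusted p = 0.018 in the fit of reads, and adjusted p = 0.565 with an estimated correlation. Of 6 genes measured in the metallothionein list, of metal-binding proteins, limma called 0 over 20 libraries (camera adjusted p = 0.00293, and adjusted p = 0.933 with an estimated correlation). Fewer than 5 were measured in the other fits, so the list was not tested there. MT1X rose from 4.14 ± 2.42 to 72.2 ± 131 CPM (4.06 ± 1.04 SE, adjusted p = 0.0257; corrected 4.64, adjusted p = 0.0365). MT1X was at 337 and 302 CPM in dexamethasone replicates 4 and 9 and at 0 to 51.6 CPM in the other 8 treated libraries. These 2 libraries also had the highest levels of the handling-stress genes FOSB (214 and 1078 CPM) and DNAJB1 (315 and 5351 CPM). The call of MT1X in the fit of reads was lost without untreated 2, untreated 6 or dexamethasone 4, with adjusted p up to 0.0638. MT2A was called only after correction (2.44, adjusted p = 0.0486).

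Of 21 measured inflammatory cytokine genes, 4 were called lower and 0 higher in both fits, and 4 were lower when adjusted over the list alone. TNFSF15, a TNF-family cytokine, fell from 36.1 ± 30.7 to 1.81 ± 3.99 CPM (-5.10 ± 1.09 SE, adjusted p = 0.0112; corrected -5.21, adjusted p = 0.0238). CSF1, the growth factor of the macrophage lineage, fell from 93.4 ± 104 to 6.99 ± 9.76 CPM (-4.11 ± 0.79, adjusted p = 0.00655; corrected -3.67, adjusted p = 0.025). LTB, lymphotoxin beta, fell by 2.93 on the log2 scale (adjusted p = 0.00534) and IL32, a cytokine of lymphocytes, was at -1.80 (adjusted p = 0.00761). After correction LTB was at -2.38 (adjusted p = 0.0336) and IL32 at -1.29 (adjusted p = 0.0489). The list had camera adjusted p = 0.00306 in the fit of reads and 9.97e-06 after correction, with adjusted p = 0.662 and adjusted p = 0.272 with an estimated correlation. The lymphocyte marker lists moved in the same direction, as given below.

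Among 21 chemokines measured in the fit of reads, 3 were called lower and 0 higher (2 higher and 4 lower adjusted over the list alone). CXCL11, on the list and not called, ranged from 0 to 469 CPM in treated libraries and from 0 to 21.1 CPM in untreated ones. CCL24, an eosinophil attractant, fell from 187 ± 240 to 8.49 ± 9.91 CPM (-4.37 ± 0.79 SE, adjusted p = 0.00525; corrected -3.99, adjusted p = 0.0112), and kept its call in all 19 fits of either kind that left out a library. CCL22 fell by 2.95 (adjusted p = 0.0312) and CCL8 was at -3.57 (adjusted p = 0.0453). After correction they were at -2.58 and -3.57, not called (adjusted p = 0.0761 and 0.074), and their calls held in 11 and 6 of the 19 fits of reads without a library. CCL22 is also on the list of dendritic cell markers, which moved in the same direction, as given below. The chemokine list had camera adjusted p = 0.018, and adjusted p = 0.652 with an estimated correlation. In the list linked to granulomas and sarcoidosis, 1 of 17 measured members was called lower, MMP9, a matrix-degrading protease (-3.69, adjusted p = 0.0499; corrected -3.25, adjusted p = 0.0963). The call of MMP9 held in 4 of the 19 fits without a library. That list had camera adjusted p = 0.00503, and adjusted p = 0.652 with an estimated correlation.

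Receptors for migration and adhesion included 6 genes called lower of 26 measured in the fit of reads and 2 after correction (8 and 6 adjusted over the list alone). ITGAL, the integrin alpha chain of LFA-1, fell from 496 ± 159 to 169 ± 61.0 CPM (-1.49 ± 0.24 SE, adjusted p = 0.0025; corrected -1.06, adjusted p = 0.0238). FPR3, a formyl peptide receptor, fell by 2.92 (adjusted p = 0.0236; corrected -2.97, adjusted p = 0.0454). The homing integrin ITGB7 (-1.47, adjusted p = 0.00865) was called lower in the fit of reads and not after correction (-0.96, adjusted p = 0.0818). Of 21 costimulatory and inhibitory genes, 2 were called lower in the fit of reads. HAVCR2, which encodes TIM-3, fell from a mean of 144 to 43.8 CPM (-1.62 ± 0.29, adjusted p = 0.00368; corrected -1.51, adjusted p = 0.0112). LGALS9, a ligand of TIM-3, fell by 1.74 (adjusted p = 0.00409; corrected -1.43, adjusted p = 0.0238). The adhesion list had camera adjusted p = 0.0312, and adjusted p = 0.726 with an estimated correlation, and the costimulatory list was not called (camera adjusted p = 0.187). Lymphocytes also express ITGAL and ITGB7, and lists of lymphocyte markers moved in the same direction, as given below.

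Markers of other cell types were measured in these monocyte isolates. Of 20 NK and cytotoxic markers, 5 were called lower in the fit of reads and 3 after correction (9 and 4 adjusted over the list alone). GZMM fell from 18.2 ± 11.6 to 1.24 ± 1.62 CPM (-3.40 ± 0.54 SE, adjusted p = 0.0023; corrected -2.74, adjusted p = 0.0125), and NCAM1, the NK marker CD56, fell by 2.33 (adjusted p = 0.00744; corrected -2.22, adjusted p = 0.0238). GZMA fell by 1.83 (adjusted p = 0.0266; corrected -1.84, adjusted p = 0.0486), a call lost in the fit of reads without untreated 6 or dexamethasone 6 (adjusted p up to 0.053). Of 22 T cell markers, 6 were called lower in the fit of reads and 2 after correction (8 and 3 adjusted over the list alone). They included the T cell receptor kinase LCK (-1.55, adjusted p = 0.00295; corrected -1.08, adjusted p = 0.0489) and the adaptor LAT (-1.96, adjusted p = 0.00911; corrected -1.64, adjusted p = 0.0369). The surface markers CD27 (-2.20, adjusted p = 0.0178) and CD5 (-1.15, adjusted p = 0.0176) were called in the fit of reads alone (corrected -1.71 and -0.71, adjusted p = 0.101 and 0.165). IL7R, the interleukin 7 receptor, is on the same list and did not fall. It ranged from 302 to 1642 CPM untreated and from 383 to 2512 CPM with dexamethasone, and was not called. The B cell list had 1 of 16 members called lower, and the dendritic list 4 of 11, among them the interleukin 3 receptor IL3RA (-1.44, adjusted p = 0.0218; corrected -1.05, adjusted p = 0.153). After correction 0 of 15 B cell and 0 of 11 dendritic markers were called. Of 11 platelet markers 0 were called, with a median of 0.41. Camera adjusted p in the fit of reads was 0.00213 for NK, 0.018 for T cell, 0.000266 for B cell and 0.018 for dendritic markers. With an estimated correlation these were adjusted p = 0.652, adjusted p = 0.726, adjusted p = 0.652 and adjusted p = 0.652. After correction the NK (camera adjusted p = 4.65e-05), B cell (1.31e-06) and dendritic lists (0.00439) were called, each with adjusted p = 0.272 with an estimated correlation, and the T cell list was not (camera adjusted p = 0.135).

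Of 9 non-classical monocyte markers, 3 were called lower in the fit of reads and 1 after correction (5 in each when adjusted over the list alone, with 1 higher after correction). They included ITGAL and SPN, the sialoglycoprotein CD43 (114 ± 29.8 to 56.5 ± 19.5 CPM, adjusted p = 0.00761), which was not called after correction (-0.60, adjusted p = 0.185). The list had camera adjusted p = 0.00718, and adjusted p = 0.652 with an estimated correlation. Of 14 classical monocyte markers, 1 was called lower, and the list was not called (camera adjusted p = 0.634). None of 16 measured markers of glucocorticoid-exposed monocytes passed the threshold in either fit by edgeR (0 and 2 when adjusted over the list alone, and 0 of 19 by limma over 20 libraries). These tests took the labels as given and had no block on the title number. They do not show that these markers stayed unchanged. CD163, the hemoglobin scavenger receptor, was at 251 ± 414 and 1179 ± 1393 CPM (2.25 ± 1.05 SE, adjusted p = 0.193). The 2 untreated libraries with raised FKBP5 held 1147 and 772 CPM of CD163, and the other 7 held 2.89 to 119. Treated libraries held 54.5 to 3862 CPM of CD163, with 71.1 and 143 in the 2 with FKBP5 at untreated levels. MHC class II genes (0 of 17 called, camera adjusted p = 0.967) and interferon-gamma response genes (0 of 30 called, camera adjusted p = 0.714) did not pass either. The median of the interferon-gamma list was -0.25, but its members CXCL9 and CXCL10 were far higher in dexamethasone 2, 3 and 8 than elsewhere. They reached 1785 and 2502 CPM in treated libraries, and 175 and 76.8 CPM in untreated ones.

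Among the strongest genes outside these lists, FCER2 fell from 13.4 ± 13.1 to 0.467 ± 0.600 CPM (-4.64 ± 0.66 SE, adjusted p = 0.000912; corrected -4.16, adjusted p = 0.00424). HSD3B7 fell from 9.44 ± 5.42 to 0.518 ± 0.693 CPM (-3.78, adjusted p = 0.000912; corrected -3.27, adjusted p = 0.0073). RASAL2, a Ras GTPase-activating protein, fell by 3.50 (adjusted p = 0.00504; corrected -3.65, adjusted p = 0.0112). LAG3, an inhibitory receptor of lymphocytes, fell by 4.32 (adjusted p = 0.00853; corrected -3.76, adjusted p = 0.0361). The cytokine gene IFNG (-4.19, adjusted p = 0.0348) and the cytokine receptor CRLF2 (-3.74, adjusted p = 0.0177) were not called after correction, at -4.28 (adjusted p = 0.0553) and -3.38 (adjusted p = 0.0542). The call of IFNG held in 11 of 19 fits of reads without a library. ABLIM3 rose from 1.09 ± 0.944 to 38.2 ± 40.3 CPM (4.97 ± 0.67 SE, adjusted p = 0.000912; corrected 5.52, adjusted p = 0.00278). ZFAS1, a noncoding host of small nucleolar RNAs, rose from 70.3 ± 15.2 to 157 ± 44.6 CPM (1.17 ± 0.17, adjusted p = 0.000912; corrected 1.75, adjusted p = 0.00278). The ubiquitin-conjugating enzyme UBE2B (0.96), the RNA polymerase I factor TAF1D (corrected 1.24), the apoptosis-linked UACA (2.10), the linker histone HIST1H1D (2.31) and the chromatin protein HMGB3 (1.95) also rose in both fits. RGS1, a regulator of G-protein signalling, rose from 102 ± 28.2 to 423 ± 307 CPM in the fit of reads (2.07, adjusted p = 0.0236; corrected 2.12, adjusted p = 0.0552), a call lost without untreated 2 or untreated 6. ACAP1, a membrane-trafficking gene of lymphocytes, fell by 1.35 (adjusted p = 0.000912; corrected -0.89, adjusted p = 0.0353). Lymphocytes also express FCER2 (B cells), LAG3 and IFNG, and lists of lymphocyte markers moved in the same direction, as given above.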

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

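The tests weighed here were chosen after the results were seen, except the random splits and the GC test at equal depth. For the genes named in these texts and for 5 library measures, the highest or lowest library of a group is listed where its gap to the next was large against the range of the group (Dixon's ratio). Chance gives about 1 in 20 groups, and 19 of 154 groups met the criterion.

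Random splits tested whether any grouping of the libraries would give as many calls. Of 100 splits of the 20 libraries, the real one included, 1 reached the 5 genes of the limma fit, and the highest other split called 1. For the fit of reads, 1 of 100 splits reached 782 genes and the highest other called 12. For the corrected fit, 1 of 100 reached 180 and the highest other called 24. Chance can be excluded for these counts as measured against these splits, which do not separate treatment from depth or library preparation.

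Untreated replicate 8 stood apart in 4 measures: 3.69 in log10 reads, 1934 genes detected, 2.97% of reads in the 10 most abundant genes and 0.348% of reads from MALAT1. Dexamethasone replicate 4 had the highest share of ribosomal protein reads, 3.50%. In log2(CPM + 1), dexamethasone replicate 9 was lowest for BCL3 (2.38), HK1 (5.68) and MYD88 (3.23). It was highest for DNAJB1 (12.39) and at 0 for RGS1 and UACA, with 238449 reads in all. Dexamethasone replicate 3 was at 0 for ITGB7 with 135108 reads, and untreated replicate 9 was at 0 for FPR3 and at 0.63 for RASAL2. FOSB was highest among untreated libraries in replicate 10 (5.59). TFE3 was highest in untreated replicate 7 (7.43) and lowest in dexamethasone replicate 8 (5.34). In 1 library labelled dexamethasone, CRLF2 was highest at 4.07 and TSC22D3 lowest at 6.09, and this was 1 of the 2 treated libraries with FKBP5 at untreated levels.

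FKBP5 was at untreated levels in 2 libraries labelled dexamethasone and raised in 2 libraries labelled untreated. Shallow sequencing is argued against for the 2 treated libraries by a test with all 19 libraries thinned to 135108 reads. Both lay below the other 8 in the mean of 22 target genes, by -0.44 in log2 at the closest (largest SD over thinnings 0.24). FKBP5, by which the 2 were picked, is in that mean, so part of the gap was selected. By the mean target level, an exchange with the untreated library of the same title digit cannot be told apart from other causes. In that mean the higher of these untreated libraries lay only -0.0722 from the lowest of the 8 treated ones, and 0.09 above it at full depth. Of 4 target genes looked at after that mean, FKBP5 (-2.68) and TSC22D3 (-1.88) argued against an exchange, PER1 (-0.05) and ZBTB16 (1.63) did not. FKBP5 was at most 117 CPM in these untreated libraries, against at least 751 CPM in the 8 treated ones. In that mean and for ZBTB16, the lowest of the 8 was dexamethasone 9. There 1 read was worth 4.19 CPM and ZBTB16 was at 21.0 CPM, so those comparisons rest on a shallow library. Correlations between libraries do not settle an exchange across title digits either. Of the 4 libraries, 3 correlated best with the library of their own digit, by at least 0.23. The fourth did not (-0.34), and the digits are not known to mark a shared donor. The correlation with GC content went with the label in all 4: -0.042 and -0.119 labelled dexamethasone, 0.150 and 0.250 labelled untreated. The first 2 lay outside the untreated range of 0.134 to 0.347, but nearer to it than most other treated libraries. An exchange after library preparation would have carried these values along, so they argue against it. They cannot decide on an earlier exchange, because preparation may have differed with the label. Steroid taken before sampling or a lack of response may give the same FKBP5 levels and was not tested.

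The second pattern was the fall of GC-rich genes and the rise of AT-rich genes in treated libraries. Lower depth is argued against as its whole cause: after thinning all 19 libraries to 135108 reads, log2 fold change and GC content still correlated across genes at -0.48. Library preparation that differed with the label may be a source, and so may a response to dexamethasone that favors AT-rich genes. In the libraries whose FKBP5 went against their labels, the correlation with GC went with the label. It was -0.042 and -0.119 in those labelled dexamethasone, and 0.150 and 0.250 in those labelled untreated. Those labelled dexamethasone lay below the range of the untreated libraries (0.134 to 0.347). They lay above the other treated libraries (-0.211 to -0.327), apart from the shallow dexamethasone 3 and 9 (-0.026 and 0.033). These values argue against a response that follows FKBP5 as the whole cause, but leave it open as a part of the cause. Other responses to dexamethasone share the label with library preparation, and neither was tested.

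The third pattern was the fall of T cell markers such as LCK and LAT, which IL7R on the same list did not share. A lower share of T cells predicts a like fall of the T cell receptor genes CD3D, CD3E, CD3G and CD247 and of CD2. Their median log2 fold change was -0.44 in the fit of reads and -0.17 after correction, while LCK was at -1.55 and LAT at -1.96 in the fit of reads. A loss of T cells cannot be told apart from none, because the median in the fit of reads lay between the bounds set for a loss and for none. Its spread (SD over the root of 5, 0.11) treats the genes as independent, while their SE over libraries was 0.234 to 0.407. After correction CD3E (0.14) and CD247 (0.11) were higher and CD3G (-0.58), CD3D (-0.21) and CD2 (-0.17) lower, with none called. Regulation of LCK and LAT within T cells was not tested.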

How the results depend on the processing

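The alternatives to the fit of reads and to the corrected fit, edgeR in place of limma, thinned reads and leaving out single libraries were chosen after seeing the data. Over all 20 libraries, where limma called 5 genes (1 higher, 4 lower), no planned setting kept the count except a 2-fold minimum. DESeq2 called 1720 (662 higher, 1058 lower), robust variances 125 (3 and 122), median centring 189 (55 and 134), quantile normalization 89 (24 and 65) and no filter 15 (1 and 14). A mean of at least 100 CPM, pseudocounts of 0.1 and 10, an adjusted p under 0.01 and a test against 1.5-fold each called 0. Leaving out the libraries apart on principal components (untreated 8, dexamethasone 3 and 9) called 1758 (456 and 1302). edgeR on the recovered reads of 20 libraries called 298 (114 and 184), and limma on reads of 19 libraries thinned to 135108 called 140 (25 and 115). Without single libraries the count ranged from 0 to 880 (0 to 117 higher, 0 to 763 lower), with 880 without untreated 8, 16 without dexamethasone 7 and 24 without dexamethasone 10. Leaving out any other library except dexamethasone 2 gave 0 to 2 genes. The cause was not tested. For lists, 13 passed with a preset correlation, and 0 with an estimated one or with fry. Under DESeq2, STAT2 (-0.73), HLA-E (-0.43), HK1 (-0.55) and UQCRC1 (-0.52) were called against the sign of the limma fit. So were HLA-E (-0.47), HK1 (-0.46) and the MHC class I list (median -0.49) without the libraries apart.

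From the 782 calls of the fit of reads (336 higher, 446 lower), the count moved to 2312 with DESeq2 (996 and 1316), 1719 with voom (638 and 1081), and 400 with a mean of at least 100 CPM (171 lower). All genes with 1 read gave 679 lower. An adjusted p under 0.01 left 138 (60 and 78), a 2-fold minimum 387 (87 higher) and a test against 1.5-fold 26 (6 and 20). Without dexamethasone 3 and 9 it called 2057 (1107 and 950), which included 778 of the 782. Without single libraries it called 438 to 1378 (182 to 701 higher, 250 to 795 lower), lowest without untreated 2, 5 and 6 and dexamethasone 6 (438, 510, 441 and 502) and highest without dexamethasone 3, 7 and 9 (1311, 1375 and 1378); 377 genes were called in every one of these fits. Against 15 lists called, 1 was past the threshold at a mean of at least 100 CPM and 0 with an estimated correlation. With fry the same 15 lists passed (adjusted p up to 0.0446) except feedback regulators (0.476), glucocorticoid receptor machinery (0.552) and ribosomal proteins (0.787). The MHC class I list, not called by camera (adjusted p = 0.112), also passed with fry as lower (adjusted p = 0.0446). The cause of these changes was not tested.

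From the 180 calls of the corrected fit (129 higher, 51 lower), an adjusted p under 0.01 left 8 (6 and 2), a 2-fold minimum 76 higher, and a test against 1.5-fold 9 (5 and 4). Without dexamethasone 3 and 9 it called 574 (408 and 166), which included 176 of the 180. Without single libraries it called 23 to 435 (14 to 301 higher, 9 to 141 lower), and only leaving out untreated 1, dexamethasone 1 or dexamethasone 9 moved the count by less than 1.5 times; 22 genes were called in every fit. Of the genes named here, 45 of 58 kept their call in all 19 such fits of reads and 9 of 40 in all corrected ones; ABLIM3 and FCER2 kept theirs wherever the filter let them be tested. Against 13 lists, 0 passed with an estimated correlation and 2 with fry. The cause was not tested.

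The labels do not pair the libraries. Correlations went with a pairing by title digit in most pairs but not in the lowest, so pairing was not settled for every library. Libraries that shared a last digit had deviations from their group means that correlated across genes at -0.05 to 0.68 in 9 pairs. All but the lowest pair were at 0.189 or more, against a median of -0.04 for other pairs, and 5 pairs were each other's best match. The main fits, permutation tests and random splits had no block, so they ignore any pairing that the digits mark. A replicate block on that digit called 29 genes in the 20-library limma fit (2 higher, 27 lower) and 874 in the fit of reads (245 and 629), 548 of them shared. In the corrected fit the block called 192 (92 and 100), 110 of them shared. Of the genes taken by the rule, the block ended the call of 6 in the fit of reads and added a call for 33. In the corrected fit it ended the call of 11 and added a call for 15.

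Depth limits genes under the floor of 3 reads, 22.2 CPM in dexamethasone 3 and 12.6 CPM in dexamethasone 9.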

Other observations

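Further fixed lists held single members past the threshold in the fit of reads. Among 29 genes of mTORC1 signalling and autophagy, 3 were called higher and 1 lower. SESN1, a stress-induced brake on mTORC1, rose from 21.9 ± 6.45 to 58.4 ± 39.1 CPM (1.48 ± 0.33 SE, adjusted p = 0.0124; corrected 1.42, adjusted p = 0.0257). FNIP1, a folliculin partner, rose by 0.65 (adjusted p = 0.0154) and the lysosomal factor TFE3 fell by 0.72 (adjusted p = 0.0212), and neither was called after correction (0.59 and -0.17). Of 28 lipid and cholesterol genes, 3 were called lower and 0 higher, including fatty acid synthase, FASN (-1.57, adjusted p = 0.00277), and the nuclear receptor PPARD (-1.08, adjusted p = 0.0206). None of these 28 was called after correction, where FASN was at -0.90 ± 0.29 SE (adjusted p = 0.0992) and PPARD at -0.56 (adjusted p = 0.235). The matrix gene COL6A2 fell by 1.98 (adjusted p = 0.0142; corrected -1.34, adjusted p = 0.118, not called) in a list with 2 of 20 members called lower and 0 of 20 after correction.

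Of 28 Toll-like receptor and inflammasome genes, the adaptor MYD88 fell by 0.93 (adjusted p = 0.0227) and the kinase IRAK4 rose by 0.80 (adjusted p = 0.0184). CD46, which protects cells from complement, rose by 0.86 (adjusted p = 0.00464), BCL3, an NF-kB cofactor, fell by 1.15 (adjusted p = 0.0136), and the interferon-stimulated LY6E fell by 1.98 (adjusted p = 0.0165). None of these 5 genes was called after correction, at -0.63 for MYD88, 0.84 for IRAK4, 0.85 for CD46 (adjusted p = 0.0558), -0.41 for BCL3 and -1.30 for LY6E. EGR2, an immediate early gene, fell by 2.70 (adjusted p = 0.00705; corrected -2.39, adjusted p = 0.037, kept in 6 of 19 corrected fits without a library), and the clock repressor NR1D2 rose by 0.79 (adjusted p = 0.0209; corrected 0.72, adjusted p = 0.104). Of 37 ribosomal protein genes, 1 was called higher in the fit of reads and 4 after correction (1 and 8 adjusted over the list alone). RPS27 rose from 441 ± 60.8 to 719 ± 225 CPM (0.75 ± 0.17 SE, adjusted p = 0.0141; corrected 0.90, adjusted p = 0.0112). The median of the list was 0.05 in the fit of reads and 0.39 after correction, with camera adjusted p = 0.00503 and 2.07e-10, and adjusted p = 0.787 and adjusted p = 0.272 with an estimated correlation.

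Hemoglobin genes summed to 56.5 to 10114 CPM over the 19 libraries other than untreated replicate 8, with no group difference detected (log2 mean 9.31 untreated and 9.80 with dexamethasone, permutation p = 0.666, adjusted p = 0.685).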
